A study of Mus musculus with 2 samples.

How the data were processed

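Gallbladder and extrahepatic bile duct tissue of adult, untreated mice was digested, live single cells were sorted by flow cytometry, and 2 droplet libraries were made with version 3 of the 10x Chromium 3' chemistry, per the labels. In this chemistry a droplet carries a bead whose oligonucleotides that capture polyadenylated RNA share 1 cell barcode of 16 bases. Reads are taken near the 3' end of each transcript. One library came from Pou2f3-/- mice (Pou2f3 KO) and 1 from littermates that kept 1 or both Pou2f3 alleles (WT), per the labels. The labels do not give the number of animals in a library. Cell Ranger and version 3 of Seurat, and the genome builds GRCm38 and mm10, are named in the submitters' processing notes. The version of Cell Ranger, the rule by which barcodes were called as cells, and filters on cells are not given in the sources used here.

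The files used here were, for each library, the deposited list of cell barcodes and the deposited list of features (gene identifier, symbol and feature type). Both lists are text and hold no measured value. The matrices of counts that belong to these lists were not analysed here. For this reason no expression level, no count of molecules per cell, no cell type, and no difference in expression or in cell composition between the genotypes is reported, and the sequencing depth of the libraries is unknown. The comparisons of expression and of cell class shares that had been planned for the case that counts were at hand were not run.

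From the barcode lists, the lines of each library were counted, and base composition and the pairs of adjacent bases were tabulated at each position. Positions are counted from 1 at the first base of the barcode as listed. Barcodes shared by both libraries were counted on the 16 bases. The number expected by chance was the product of the barcodes of both libraries divided by the size of the pool they were drawn from. The pool was first taken as about 6800000 barcodes, a size for the manufacturer's list that is recalled from memory and is not in the files. A second pool was built from the data as every combination of a 7-base start with a 9-base end seen in either library. Observed and expected numbers were compared with a two-sided exact hypergeometric test, and intervals of 95% on counts are exact Poisson intervals. These cover counting error only. With 1 library per genotype, none of these tests compares the genotypes. The calculation was tested on simulated data: 50 pairs of libraries of the real sizes, drawn from the same starts and ends, shared 288 barcodes on average against 287.6 expected, and with 200 barcodes copied from one library into the other the mean excess was 199. This checks the code only. It does not test whether the real barcodes were drawn evenly from all combinations of starts and ends.

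From the feature lists, identifiers were matched to GENCODE release M21, an annotation of GRCm38. Of the 27998 features, 27722 identifiers were found there, 26573 of them with the same symbol. Coordinates are those of GENCODE M21 on GRCm38. The annotation behind the feature lists is not named in the sources used here and may differ from it in gene models. Symbols of 24 gene lists, fixed before the data were examined, were looked up by exact match. The genes named in the text are members of these lists, apart from the neighbours and sequence partners of such genes, which were chosen after the values were seen. The last 500 bases of every transcript in GENCODE's basic set were cut into stretches of 50 bases for the list members, and the share of stretches found in a transcript of any other M21 gene was computed. The same was done for 500 protein-coding features drawn at random, 498 of which had such a transcript. This check of 3' sequence was added after the files had been seen. It covers annotated transcripts only and not the rest of the genome. Calculations used Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1.

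The alternatives were to count distinct sequences, to leave out barcodes within 1 mismatch of another, to match barcodes with their suffix or within 1 mismatch, to take all 16-base sequences as the pool, and to match symbols without regard to letter case or through older names. For the 3' sequence, windows of 300 and 1000 bases, stretches of 90 bases and a restriction to other features were tried.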

Results

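The series compared the cells of the gallbladder and extrahepatic bile duct between mice with and without Pou2f3, the transcription factor on which the development of tuft cells depends. Tuft cells are rare chemosensory epithelial cells. The tissue was digested whole and sorted for live cells, and the labels give epithelial, immune and stromal cells as the content of each library, which could not be checked without counts. There was 1 library per genotype. The data used here were the cell barcodes and the features of each library, without the counts that join them. They give the number of barcodes listed, the relation between both sets of barcodes, and the genes that could be counted. They do not show which genes or cell types differed between Pou2f3 KO and WT tissue.

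The WT library listed 30901 cell barcodes (95% Poisson interval 30557 to 31247) and the Pou2f3 KO library listed 34322 (33960 to 34687). The KO library thus held 11.1% more barcodes, a ratio of 1.111 with a counting interval of 1.094 to 1.128. This interval leaves out differences in the number of cells loaded and in the calling of cells, and no replicate library was at hand to measure them. The numbers are high for a single channel of this chemistry, and how many of the listed barcodes hold a cell was not checked, since the rule by which they were chosen is not given in the sources used here. They are therefore given as numbers of listed barcodes, and the 11.1% cannot be read as a difference in cell number. Every barcode of both libraries had 16 bases and the same suffix, no barcode was listed again within its library, and no barcode lay within 1 mismatch of another.

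The barcodes of both libraries were built alike. Between positions 8 and 9, 4 of the 16 possible base pairs occurred, AG, CA, GT and TC, each in 24.3% to 25.7% of the WT barcodes and 24.8% to 25.4% of the KO barcodes. At every other pair of adjacent positions all 16 occurred. The share of a single base at a single position ranged from 22.8% to 28.4% in the WT library and from 22.7% to 28.1% in the KO library. Each library contained the same 960 distinct 7-base starts. The WT library contained 3840 distinct 9-base ends, all of them among the 3841 of the KO library. All combinations of the 960 starts with the 3841 ends form a pool of 3687360 barcodes.

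The libraries had 281 barcodes in common (95% Poisson interval 249.1 to 315.9), which is 0.909% of the WT barcodes and 0.819% of the KO barcodes. With a pool of about 6800000 barcodes, 156.1 shared barcodes were expected by chance, and the observed number was 1.8 times that (two-sided exact hypergeometric test, p = 2.1e-19). With the pool of 3687360 built from the starts and ends, 287.6 were expected, and the observed number did not differ detectably from it (two-sided exact hypergeometric test, p = 0.72). The overlap alone implied a pool of about 3770000 barcodes, with an interval of 3360000 to 4260000.

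**Figure D1:**
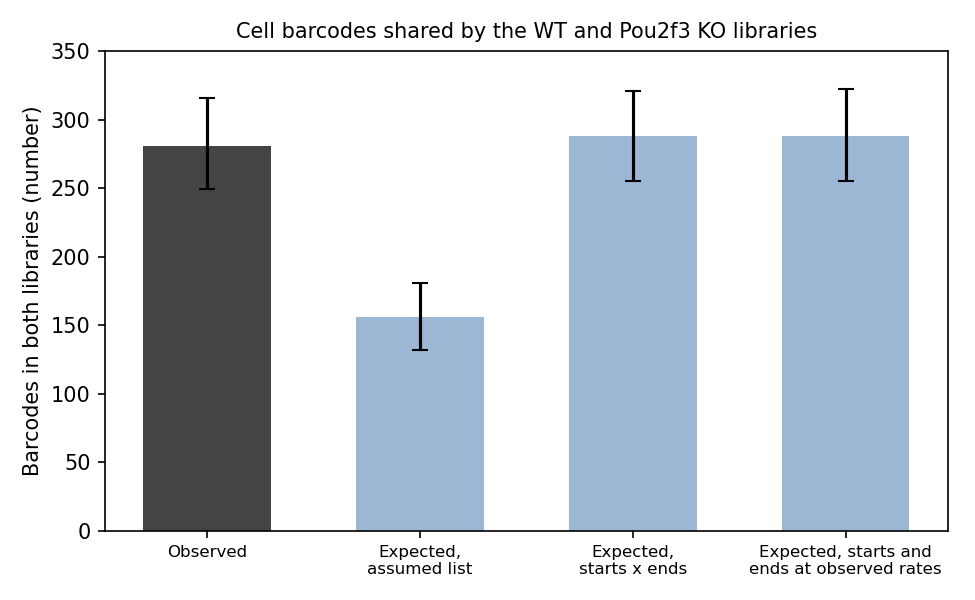
Number of cell barcodes present in both libraries, as observed (dark bar, with its 95% Poisson interval) and the number given by chance (light bars, with the central 95% of the chance distribution) for a pool of about 6800000 barcodes, for the pool of starts combined with ends, and for starts and ends drawn at the rates each library showed. The observed 281 lies above the 156.1 of the first pool and close to the 287.6 of the second.

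Both libraries were set against an identical list of 27998 features in the same order, all of the gene expression type. Any gene that could be counted in one genotype could therefore be counted in the other. By GENCODE M21, 21631 of the features were protein-coding genes, out of 22028 such genes in that annotation, and 13 lay on the mitochondrial chromosome. Long intergenic non-coding RNAs made up 3502 features and antisense genes 2282. None of the 226 T cell receptor genes and none of the 268 immunoglobulin genes of GENCODE M21 was among the features.

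Pou2f3 (ENSMUSG00000032015), the targeted gene, was a feature of both libraries. It lies on the minus strand of chromosome 9 from 43123939 to 43210369 (GRCm38), a span of 86.4 kb. Both of its basic transcripts have 13 exons. They share a last exon from 43123939 to 43125130, of which the part from 43123939 to 43125093, 1155 bases, is 3' UTR. No other annotated gene overlaps it. The nearest features are Tmem136, 7.37 kb beyond the 3' end, and Oaf, 10.9 kb beyond the 5' end, both on the same strand. None of the stretches of 50 bases in its last 500 bases occurred in another annotated gene. Which part of Pou2f3 was deleted is not given in the sources used here. If the last exon was kept in the mutant allele, 3' reads from it would not check the genotype of the KO library.

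**Figure D2:**
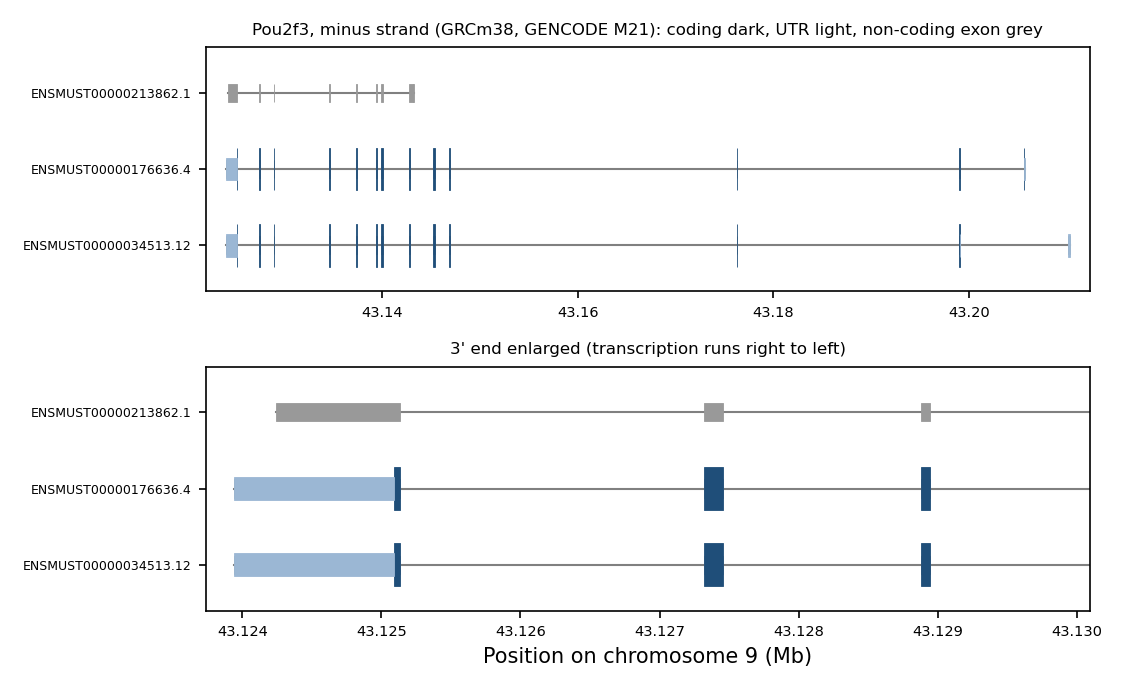
Annotated transcripts of Pou2f3 on chromosome 9 (horizontal axis, Mb, GRCm38), the whole gene above and its 3' end below, with coding exons dark, UTRs light and exons of the non-coding transcript grey. The 3' UTR of 1155 bases, where 3' reads would fall, is shared by both coding transcripts.

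Of the 266 distinct genes on the 24 lists, 262 were features under the symbol written on the list, and 22 lists were complete. All 32 tuft cell genes were present, among them Dclk1, the kinase used to mark tuft cells (ENSMUSG00000027797, chromosome 3, 55242364 to 55539068), Trpm5, the cation channel of taste signalling (ENSMUSG00000009246, chromosome 7, 143069153 to 143094642), and Il25, the tuft cell cytokine (ENSMUSG00000040770, chromosome 14, 54932695 to 54935837). All 25 cholangiocyte genes were present, as were the 12 genes of bile acid sensing and transport, which include the bile acid receptor Gpbar1 (ENSMUSG00000064272, chromosome 1, 74278550 to 74279624). The 11 genes of eicosanoid synthesis and response, the 11 of taste transduction, the 11 of type 2 immunity and the 12 neutrophil attractants and related cytokines were complete. So were the lists for macrophages and monocytes (14), dendritic cells (11), B and plasma cells (9), mast cells, basophils and eosinophils (10), fibroblasts (11), endothelium (10), smooth muscle and pericytes (9), nerve and glia (8), mesothelium (5), hepatocytes (7) and erythrocytes (5). The lists for dissociation stress (12), proliferation (10), sex-linked genes (6) and interferon response (9) were complete too. Presence on the list says that a gene could be counted, and nothing of its expression.

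The 2 incomplete lists were those for neutrophils and for T, NK and innate lymphoid cells. Of the 18 neutrophil genes, 17 were found. Acod1, the itaconate-producing enzyme of activated myeloid cells, was missing under this symbol, but its identifier (ENSMUSG00000022126, chromosome 14, 103046977 to 103056573) was listed under its older name Irg1. Of the 20 T, NK and innate lymphoid genes, 17 were found. The 3 others were the T cell receptor constant genes Trac (chromosome 14, 54220521 to 54224206), Trbc1 (chromosome 6, 41538218 to 41539881) and Trdc (chromosome 14, 54142851 to 54148868), and neither their identifiers nor older names were listed. T cells could be marked by Cd3e, a chain of the receptor complex (ENSMUSG00000032093, chromosome 9, 44998740 to 45009627), which was a feature.

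Over the lists, 6 of the 263 identifiers tested (2.28%) shared at least 50% of their 3' sequence with another annotated gene, against 32 of 498 randomly drawn protein-coding features (6.43%). Of these, 4 were the haemoglobin genes of the erythrocyte list. Hba-a1 (88.9% of stretches) and Hba-a2 (85.4%) shared sequence with each other, as did Hbb-bs (64.7%) and Hbb-bt (64.5%). Mzb1, a plasma cell gene, shared 99.8%, chiefly with an overlapping gene that was not a feature, and 0% with other features. Serpina1a, a hepatocyte gene, shared 55.6%, and 31.1% with other features. None of the 32 tuft cell genes, the 25 cholangiocyte genes or the 17 neutrophil genes tested reached 50%. Acod1, listed as Irg1, was not tested. Among myeloid markers, Ly6c2 shared 34.8%, chiefly with Ly6c1, and Lyz2 shared 16.9%, chiefly with Lyz1. Itgam, the integrin used to mark myeloid cells, was the symbol of 2 features, ENSMUSG00000030786 (chromosome 7, 128062640 to 128118491) and ENSMUSG00000108596 (chromosome 7, 128062683 to 128128160). They overlap on the same strand, and M21 calls the second Gm49368. Of the 3' stretches of the first, 19.7% occurred in another annotated gene, chiefly the second, so some of its reads could be split or lost between both. Over all features, 56 symbols stood for more than 1 identifier.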

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

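The number of barcodes per library, the number shared and the number of list members found kept their values or moved by 1 gene under the alternatives set before the data were examined. The WT library kept 30901 barcodes and the KO library 34322 when distinct sequences were counted and when barcodes within 1 mismatch of another were left out. The libraries shared 281 barcodes with the suffix and within 1 mismatch. The counts per library could not have moved, since no barcode was listed again or lay within 1 mismatch of another in its library. The match with the suffix could not differ either, since all barcodes carried the same suffix. The match within 1 mismatch may not have been free to differ, since neither library held barcodes that close to each other. List members rose from 262 to 263 with older symbols, through Acod1. The number of shared barcodes expected by chance depended on the pool: it was 156.1 for the assumed list, 0.2469 for all 16-base sequences, 287.6 for starts combined with ends, and 288 for starts and ends at their observed rates. The last 2 pools were chosen after seeing the data. The count of list members with at least 50% shared 3' sequence, also added after seeing the data, was 6, and 4 to 6 under its alternatives. Hba-a1 and Hba-a2 were among them in every setting tried, whereas Serpina1a, Mzb1, Hbb-bs and Hbb-bt each dropped out in at least 1. The other filters on cells considered for expression and for cell class shares were not run, since no counts were used. Without counts the depth of the libraries is unknown, and with 1 library per genotype no replicate could be left out.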

Other observations

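All tests in this part were chosen after the overlap of the barcodes had been seen. The libraries shared 281 barcodes, 125 more than the assumed list of about 6800000 would give. Reads of one library present in the other would raise the overlap above what the pool of starts and ends gives, if their barcodes were listed in both. The overlap cannot bear on cells mixed before they entered droplets, which would get barcodes of their own. Nor can it bear on stray reads too few for a barcode to be listed. The overlap minus the number from the pool was -6.63. The upper limit of the interval leaves room for at most 28.2 barcodes listed in both through such a transfer of reads, or 0.091% of the WT barcodes. This is too few for the excess of 125. A pool smaller than the assumed list gave 287.6, inside the interval of the observed number, and is a candidate explanation for the excess. If all 960 starts combined with every end, a list of about 6800000 would need many more ends than the 3841 seen. These 3841 occurred on average 8.05 times each in the WT library and 8.94 times in the KO library. Even draws of this many barcodes from the whole assumed list would leave few ends unseen. The ends seen thus argue against even draws from that whole list. Starts and ends were used about evenly: the variance of the number of barcodes per start was 1.02 times its mean in the WT library and 0.95 times in the KO library. No biological explanation was tested, since a barcode is assigned by chance to a droplet.

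Given the pool of 3687360, and if every listed barcode stood for 1 droplet with a cell, about 129 WT barcodes (0.42%) and 160 KO barcodes (0.47%) are expected to have been carried by beads in 2 such droplets. This is a calculated number for collisions among listed barcodes only. It leaves out beads in droplets that are not listed, whose number is not known here, and droplets that took up more than 1 cell.

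Of the 3539 distinct 7-base ends, 302 occurred with 2 pairs of bases at positions 8 and 9, each the complement of the other, and 3237 with 1. One hypothesis is that some droplets were listed under 2 barcodes that differ by this complement. Within the libraries 56 such couples were found, 25 in WT and 31 in KO, against 45.5 expected by chance (one-sided exact Poisson test, p = 0.072). Between the libraries, where no droplet can be shared, 48 were found against 45.2 expected. Such couples could be found only at the 604 of 3841 9-base ends whose complement end was also seen. There the number of couples is too small to tell chance and double listing apart. Double listing elsewhere would have given other ends a complement pair too, yet 3237 of the 3539 7-base ends occurred with 1 pair. This argues against double listing that affects all ends alike. It does not bear on double listing limited to the 604 ends.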
